A study of Mus musculus with 5 samples.

How the data were processed

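Total RNA of mouse embryonic stem (ES) cell lines and their derivatives was measured on 5 one-colour expression arrays. Per the labels' protocols, the RNA was extracted with a commercial kit and amplified to amino allyl antisense RNA, and dye coupling and fragmentation followed the instructions of the array maker, Toray. The values analysed are the probe intensity values that the authors deposited, on a linear scale, for 22871 probes per array. Scanner settings, background correction, normalization and the rule by which a probe received no value are not given in the sources used here. The linear scale was read from the values, which are all positive and reach 99969.83 to 118793.73 per array. The median over the listed probes was 50 on each of the 5 arrays (49.995 to 50.015), so the deposited values share a common median, and the method behind it remains unknown. The values are of 1 colour and not centred per gene, so no direction had to be settled. The lowest listed value lay between 2.96 and 3.66, and 1392 to 2084 probes per array (6.09% to 9.11%) held no value. Probes without a value on 1 array had a median of 6.37 on their other arrays, and 36 of the 3987 probes with any empty cell reached 100 somewhere. An empty cell was therefore read as a value under the floor or removed by the authors, and was not filled in.

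The samples fall into 4 groups by their labels: line 21 ES cells without 4-hydroxytamoxifen (4OHT), line 21 ES cells with 4OHT, Akt-spheres (1 array from line 21 and 1 from line 42) and ES-like cells reverted from line 21 spheres. Only the Akt-spheres have more than 1 array, and line and replicate cannot be told apart there. The labels name no hybridisation batch. Nothing says whether the arrays come from repeated cultures, so each p-value measures only the spread between these arrays, which may in part be technical. The number of arrays limits the precision of every comparison.

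Probe names came from the platform's annotation: 16264 probes had 1 gene symbol, 0 had several and 6607 had none. Of 16087 array symbols, 12239 matched a current symbol in the RefSeq gene table of GRCm38.p6, 3787 were updated through a single synonym and 61 were kept as given. The table was used for names only and no coordinates were taken from it. The 16032 genes included 221 with several probes, each represented by the probe with the highest mean over the 5 arrays. Pou5f1 and Sox2 were not analysed here.

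Values were taken to log2(value + 1), where 1 is the pseudocount, and each array was centred on its median over the 18884 probes listed on all arrays. Centring moved the arrays by -0.08 to 0.06 log2 units. A fold difference below is on the log2(value + pseudocount) scale and understates the change of dim probes. A gene entered a comparison if it had a value on all arrays compared and reached the 40th percentile of at least 1 of them, which lay at an intensity of 28.6 to 29.3.

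Of the 7 comparisons, 3 set single arrays against each other and have no replicate check, so genes at least 2-fold apart were counted. As an alternative for 2 of them, those of ES cells with 4OHT and of reverted cells against ES cells without 4OHT, limma was run with the spread of the 2 sphere arrays. The other 4 used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment, threshold 0.05). For spheres against ES cells without 4OHT, against ES cells with 4OHT and against reverted cells, the fit had a mean for each of the 4 groups and 1 residual degree of freedom, so each lone array was assumed to vary as the 2 sphere lines do. Beside it stands the count of genes at least 2-fold apart the same way in both sphere lines. For spheres against the 3 ES-type arrays together, the fit had 3 residual degrees of freedom, and its spread holds the differences between those conditions too. To describe reversion, genes were chosen as at least 2-fold apart between line 42 spheres and ES cells with 4OHT and measured on the other arrays, so that choice and measurement share no array.

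The 31 gene lists cover core, naive and primed pluripotency, early and late germ cells, primitive endoderm, mesoderm, blood and endothelium, neuroectoderm, trophectoderm, OP9 stroma, OP9-type adipocytes, embryonic fibroblasts, FoxO targets, the Akt pathway, p53 targets, glycolysis and hypoxia, sterol and lipid synthesis, the cell cycle, DNA methylation, histone modifiers, imprinted genes, the 2-cell-like state, Hox genes, Wnt targets, LIF and BMP signalling, Myc targets, interferon response, endoplasmic reticulum (ER) and amino acid stress, adhesion and epithelial-mesenchymal transition, and housekeeping controls. Some genes belong to more than 1 list. For each list with at least 3 compared members, the median log2 difference was placed among 10000 random lists of the same size matched on mean expression, and is called higher or lower where it lies outside the central 95% of them. This percentile describes these arrays and is not a p-value over replicates. Beside each tested comparison, members past limma's threshold over all genes and adjusted over the list alone were counted.

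Genes named in the text follow a rule: 20 genes of pluripotency, germ cells and Akt wherever measured, per comparison the 10 genes with the largest difference in each direction (for spheres, 2-fold in both lines), and up to 4 members of each list with the largest difference. A few others are named as chosen after their values were seen. Groups, comparisons, lists, filters, this rule and the alternatives were fixed before the data were examined, except the setting that replaces empty cells and the tests of the closing section.

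The limma fits, the 2-fold rule and the list percentiles were tested on simulated data with known answers. For spheres against the 3 ES-type arrays, with 10589 genes, limma recovered 63 of 100 genes changed 4-fold and 91 of 100 changed 16-fold, and called 2 unchanged genes. The rule of 2-fold in both lines recovered 97 and 99 of them and called 168 unchanged genes. For spheres against 1 ES cell array, with 10262 genes, limma recovered 0 of 100 at 4-fold and 0 of 100 at 16-fold, while the 2-fold rule recovered 86 and 100 and called 563 unchanged genes. Of 100 simulated lists without a shift, 7 lay outside the central 95%. Alternatives tried were quantile normalization, no centring, another pseudocount, no filter or a stricter one, the mean of a gene's probes, an intensity trend in eBayes, a 3-fold threshold and leaving out each array where that was possible. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.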

Results

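Gene expression was measured in mouse embryonic stem (ES) cells that carry a myristoylated Akt kinase fused to a modified estrogen receptor, which 4-hydroxytamoxifen (4OHT) switches on. Of the 5 arrays, 1 came from line 21 ES cells without 4OHT, 1 from line 21 ES cells with 1 µM 4OHT, 2 from Akt-spheres and 1 from ES-like cells derived from line 21 spheres and grown on fibroblast feeders (reverted cells). Akt-spheres are floating colonies induced and expanded on OP9 stromal cells with 1 µM 4OHT, and came once from line 21 and once from line 42. The series asks whether Akt activation moves ES cells toward a state like that of primordial germ cells (PGCs) and whether such cells return to an ES-like state. Each array held 22871 probes with a summed intensity of 15.2 × 10⁶ to 19.3 × 10⁶, of which the brightest 100 probes took 29.9% to 32.5%. Over 10589 genes, Pearson's r was 0.978 between ES cells without and with 4OHT, 0.957 between ES cells without 4OHT and reverted cells, and 0.938 between the sphere lines. It was 0.901 and 0.914 between ES cells without 4OHT and the spheres of lines 21 and 42. These correlations are across genes, which are not independent replicates.

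Spheres were first compared with the 3 ES-type arrays together (n = 2 and n = 3), which asks what sets both sphere lines apart from every ES-like culture. Klf4, Klf5 and Tbx3, transcription factors of the naive pluripotent state, fell in spheres, while 5 members of the glycolysis and hypoxia list rose. Nr0b1, a nuclear receptor tied to ES cell self-renewal, fell 37.5-fold (log2 -5.23, SE 0.27, limma adjusted p = 0.00432), from intensities of 3105 to 4854 on the ES-type arrays to 106 and 104 on the sphere arrays. Klf4, another naive-state factor, fell 11.4-fold (log2 -3.51, SE 0.30, limma adjusted p = 0.00962). Fabp4, a fatty acid carrier of adipocytes and macrophages, rose 26.3-fold (log2 4.72, SE 0.25, limma adjusted p = 0.00432), from 4.63 to 6.07 on ES-type arrays to 183 and 143 in spheres. Nanog, a core pluripotency factor, read 5479.7 and 3839 in ES cells without and with 4OHT, 4538 in reverted cells and 5523 and 4003 in spheres (log2 0.04, SE 0.30, limma adjusted p = 0.958).

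Of 10589 genes tested, limma called 102 higher and 156 lower in spheres, with 2001 at an unadjusted p under 0.05 against 529.45 by chance. The other genes with the largest falls past limma's threshold were Ooep (log2 -5.72), part of the maternal complex of oocytes, Manba (-5.24), a lysosomal mannosidase, Pla2g1b (-5.21), a secreted phospholipase whose other probe read -0.80, Morc1 (-5.14), a transposon-silencing gene of male germ cells, and Acsbg3 (-5.03). The largest rises were those of Mogat2 (5.04), an acyltransferase of triglyceride synthesis, Pygl (4.98), which breaks down glycogen, Fabp4, Xlr3b (4.35), Rab6b (4.29), a Golgi traffic GTPase, Fitm1 (4.17), a fat storage protein, Smarca2 (3.81), a chromatin remodelling ATPase, Pkdcc (3.79) and Gstm5 (3.77), a glutathione transferase. Some of the largest differences missed the threshold, such as those of Zfp42, an ES cell zinc-finger gene (log2 -5.51, SE 0.96, limma adjusted p = 0.0502), Dppa4 (log2 -5.68, limma adjusted p = 0.140), Rps4l (-6.14), a probe annotated to Rpl10 (-5.58) and Ccnd2 (4.18), a G1 cyclin. Gpx2 and Zfp57, a zinc-finger protein that protects imprints, had no value on either sphere array and read 45.9 to 438.9 and 42.0 to 65.2 on the ES-type arrays, while Gad2 read 68.5 and 46.9 in spheres and had no value elsewhere. These 3 were chosen after their values were seen.

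Core pluripotency genes had a median log2 difference of -1.97 over 14 measured members, of which limma called 4 lower (Nr0b1, Dppa5a, Fgf4 and Tdgf1) and 9 adjusted over the list alone. In both lines 9 members were at least 2-fold lower. Nanog (log2 0.04) was not among them, nor was Sall4, at 41.2 and 35.0 in spheres against 34.5 to 47.1. Zfp42 and Fgf4 also belong to the naive list, and Pou5f1 and Sox2 were not analysed. Naive pluripotency genes had a median of -1.94 over 22, with 6 called lower (Manba, Tbx3, Fgf4, Mras, Klf4 and Klf5) and 13 adjusted over the list alone. Tbx3 fell from 322 to 659.9 on the ES-type arrays to 14.2 and 15.9 in spheres. The glycolysis and hypoxia list had a median of 0.32 over 26, and 5 members rose, also adjusted over the list alone: the hypoxia-inducible Ankrd37 (log2 3.61) and Adm (3.58), the oxygen-sensing prolyl hydroxylases Egln3 (3.60) and Egln1 (2.20), and the oxidoreductase Ero1a (2.18). Late germ cell genes had a median of -0.49 over 24 members, with Sycp3 of the synaptonemal complex (log2 -3.49) and the egg coat gene Zp3 (-3.48) falling and 2 adjusted over the list alone. In LIF and BMP signalling (median -0.50 over 19), Stat3 (-2.41) and its target Pim1 (-1.70) fell, 4 adjusted over the list alone. Primitive endoderm genes had a median of -0.93 over 8, a call lost with a stricter filter on dim probes. In that list Trf, the iron carrier transferrin, rose (2.31) and Gata6 fell (-2.37), 1 higher and 3 lower adjusted over the list alone.

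Of the early PGC list limma called only Dppa5a lower (log2 -4.34), 1 adjusted over the list alone. The list's median of -0.16 over 22 members lay within the central 95% of random lists. In both sphere lines 2 of its members were at least 2-fold higher and 4 lower, Dppa5a among them. Tfap2c, a PGC specification factor, was 2.52-fold higher in spheres (log2 1.34, SE 0.36, limma adjusted p = 0.127) and Nanos3, a PGC survival gene, 2.58-fold higher (log2 1.36, SE 0.41, limma adjusted p = 0.156). The other PGC specification genes Prdm14 (log2 0.65, limma adjusted p = 0.218) and Prdm1 (log2 -0.51, limma adjusted p = 0.623) also did not pass. Kit, a receptor of germ cells, had a log2 difference of 2.36 (limma adjusted p = 0.256), Dppa3 of 1.54 (0.684), Ifitm3 of -0.71 (0.314), Alpl of -0.84 (0.227), Ddx4 of -0.07 (0.901) and Dazl of -1.14 (0.416). For the primed epiblast marker Fgf5 the values were 2.36 and 0.196, for the mesoderm factor T 0.38 and 0.922, for Esrrb -1.51 and 0.0707, for Dnmt3b -1.67 and 0.163 and for Akt1 0.43 and 0.730.

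Other lists outside the central 95% were mesoderm (median log2 0.56 over 16, limma 0 at adjusted p of 0.05, 0 adjusted over the list alone, call lost with no filter), adipocyte genes (1.03 over 5, Fabp4 called, 1 alone), primed epiblast (-0.91 over 15, 0 called, 1 higher and 2 lower adjusted over the list alone) and DNA methylation (-0.52 over 17, 0 called, 2 alone). So were ER and amino acid stress (-0.43 over 16, the lipoprotein receptor gene Vldlr higher at 3.31, 1 alone) and adhesion (-0.35 over 17, the integrin Itga6 lower at -2.17, 2 alone). Within the central 95%, single members were called in the lists of blood and endothelium (Gata2, log2 2.59), OP9 stroma (Thy1 -3.97 and Acta2 -2.77), the Akt pathway (Eras -4.78, a Ras protein of ES cells that activates PI3K), p53 targets (Pmaip1 -4.42) and Wnt and Myc targets (Myc -2.57). Adjusted over the list alone, 2 members passed for blood and endothelium, OP9 stroma, sterol and lipid synthesis, Wnt targets and Myc targets each, 1 for FoxO targets, the Akt pathway and p53 targets each, 2 higher and 1 lower for trophectoderm, and 1 higher and 3 lower for interferon response. For neuroectoderm, embryonic fibroblasts, the cell cycle, histone modifiers, imprinted genes and Hox genes the count was 0. Of the 14 housekeeping controls (median -0.07), 0 were called, also adjusted over the list alone. Without the array of ES cells without 4OHT, limma called 0 genes, and without that of ES cells with 4OHT 32, of which 31 were among the 258. It called 148 without the line 21 sphere array and 93 without that of line 42, with 84 and 62 shared.

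**Figure D1:**
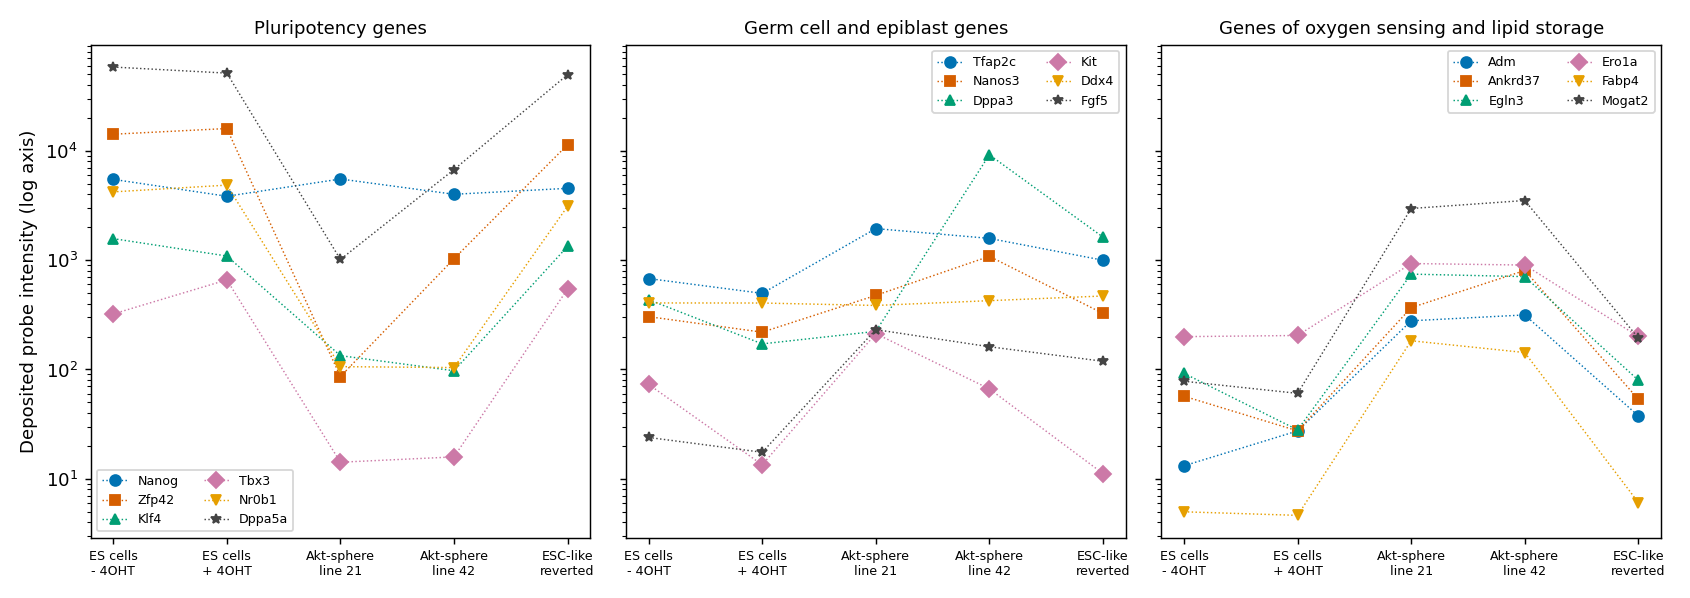
Deposited probe intensity (log axis) on each of the 5 arrays for 18 genes in 3 panels, 1 symbol per gene, with dotted lines that only join the points of a gene. Nr0b1 and Klf4 lie lowest on both sphere arrays, Nanog stays between 3839 and 5523 on all 5, Dppa3 reaches 9198 in line 42 spheres, and Fabp4 reads 183 and 143 in spheres against 4.63 to 6.07 elsewhere.

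Spheres were then set against line 21 ES cells without 4OHT. ES cells of line 42 were not analysed here, so for the line 42 spheres a difference between the lines and one between spheres and ES cells are mixed. Naive pluripotency genes had a median log2 difference of -2.86 over 19 members and core pluripotency genes of -2.30 over 14, with 12 and 9 at least 2-fold lower in both sphere lines. Bmp4, a growth factor of ES cells, was lower by -5.18, with 903 in ES cells and 75.5 and 7.99 in spheres. Mogat2 was 38.8-fold, Pygl 31.9-fold, Xlr3b 29.3-fold, the complement inhibitor Cd59a 26.2-fold and the vasodilator peptide gene Adm 19.9-fold higher. In both lines 464 genes were at least 2-fold higher and 618 at least 2-fold lower, 10.5% of 10283. In simulated data for this comparison, the same rule called 563 unchanged genes of 10262 simulated. The split was 550 to 549 under quantile normalization and 545 to 553 without centring. Further top genes were Smarca2 (log2 4.64), Rab6b (4.62), Chst1 (4.58) and Lhpp (4.35) on the higher side. On the lower side were Rps4l (-6.37), Dppa4 (-6.21), Ooep (-6.07), Khdc3 (-5.70), also of the maternal complex of oocytes, Zfp42 (-5.64), Hsd17b14 (-5.45) and Myo1f (-5.45). limma, with 1 residual degree of freedom, called 0 genes (964 at an unadjusted p under 0.05, 514.15 by chance, smallest adjusted p = 0.182). Taking 1 sphere array alone, 1890 genes lay 2-fold apart without line 21 and 2264 without line 42.

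De novo DNA methyltransferases were lower in both sphere lines against ES cells without 4OHT: Dnmt3a read 686 in ES cells and 154 and 122 in spheres, Dnmt3b 5767 against 1890.3 and 829, and their cofactor Dnmt3l 4218 against 176 and 1909. Their list (median -0.35) lay within the central 95%. Mesoderm genes were higher (median 1.02 over 15, 2 at least 2-fold in both lines), among them Wnt3 (1.48), while Msx2 (2.12) and Msx1 (1.76) were 2-fold higher in line 21 spheres alone. Trophectoderm genes had a median of 0.82 over 8 (3 higher in both lines, 0 alone), adipocyte genes of 1.36 over 5 (3 higher in both lines, 1 adjusted over the list alone) and imprinted genes of 0.34 over 16 (3 higher in both lines, such as Peg3 at 3.05, and 0 lower). Lower lists were primed epiblast (-0.68 over 15, 1 higher and 1 lower adjusted over the list alone), in which 4 members were lower and 2 higher in both lines, Fgf5 by 7.41-fold, late germ cells (-0.40 over 22, 5 lower in both lines, 3 adjusted over the list alone), LIF and BMP signalling (-0.67 over 19, 5 lower in both lines, 0 alone), primitive endoderm (-0.87 over 7, 1 higher and 1 lower alone) and interferon response (-0.41 over 13, 0 alone). The call of primitive endoderm was lost with no filter and with the stricter one, that of interferon response with the stricter one. For core and naive pluripotency, 3 and 8 members passed limma adjusted over the list alone, while over all genes it called 0 in every list. In the glycolysis and hypoxia list (0.15 over 26), 8 members were 2-fold higher and 1 lower in both lines, and 7, all higher, passed adjusted over the list alone.

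Against ES cells without 4OHT, 18 other lists lay within the central 95% of random lists. Median log2 differences were -0.15 for early PGCs, in which 1 member was 2-fold higher and 5 lower in both lines, 0.33 for OP9 stroma, 0.30 for embryonic fibroblasts, -0.03 for neuroectoderm, -0.42 for blood and endothelium and -0.70 for the 2-cell-like state. They were -0.11 for FoxO targets, -0.13 for the Akt pathway, 0.02 for p53 targets, -0.22 for Myc targets, 0.39 for Wnt targets and 0.27 for Hox genes. They were 0.26 for sterol and lipid synthesis, -0.08 for the cell cycle, -0.25 for histone modifiers, -0.15 for ER and amino acid stress, -0.34 for adhesion and -0.21 for housekeeping controls. Among these members, Gata2, a blood stem cell factor, was higher by 3.29, the Polycomb gene Eed lower by -1.99, and the matrix gene Mgp read 328 in line 21 spheres against 10.1 in those of line 42 and 4.84 in ES cells.

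**Figure D2:**
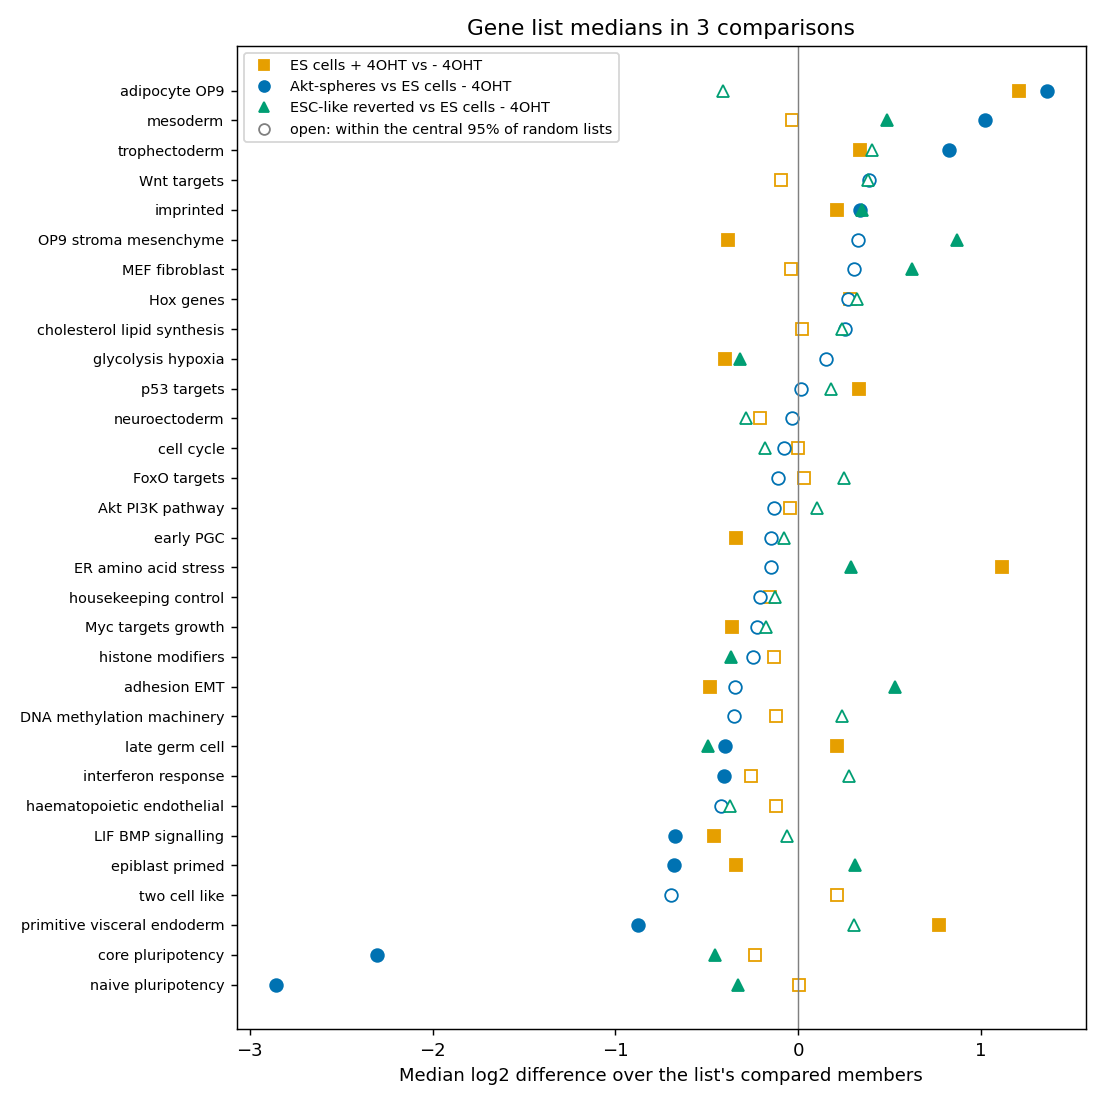
Median log2 difference over the compared members of each gene list (horizontal axis, one list per line) for ES cells with against without 4OHT (squares), spheres against ES cells without 4OHT (circles) and reverted cells against ES cells without 4OHT (triangles). Filled symbols lie outside the central 95% of random lists and open symbols within; naive and core pluripotency reach -2.86 and -2.30 in spheres, and ER and amino acid stress 1.11 with 4OHT.

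Against ES cells with 4OHT, which share the active kinase, the same direction of pluripotency genes was seen (naive -2.42 over 20 with 12 lower in both lines, core -1.90 over 14 with 8). Tfap2c was 3.68-fold, Nanos3 3.41-fold, Kit 8.68-fold and Fgf5 11.0-fold higher in spheres, each at least 2-fold in both lines, and Alpl, an alkaline phosphatase of PGCs and ES cells, was 2.17-fold lower. Against ES cells without 4OHT, Tfap2c was 2.45-fold higher, also at least 2-fold in both lines. Nanos3 (2.24-fold) and Kit (1.54-fold) did not reach 2-fold in both lines there. Nanos3 was at log2 0.60 in line 21 and Kit at -0.23 in line 42 spheres. Kit read 73.0 in ES cells without and 13.4 with 4OHT. Against ES cells with 4OHT, the early PGC list lay within the central 95% (0.15 over 22, 4 higher and 3 lower in both lines, 0 adjusted over the list alone), with Prdm1 at 0.10 and Ifitm3 at -0.29. The largest differences included Mogat2 (54.8-fold), Ccnd2 (35.7-fold), Fabp4 (30.2-fold), Egln3 (log2 4.71), Galnt12 (4.68), the receptor ligand Apln (4.55), Gstm5 (4.47) and the translation regulator Cpeb1 (4.35) on the higher side. Nupr1, a stress-response gene (-6.45), Manba (-5.75), the junction gene Jam2 (-5.74), Zfp42 (-5.68) and Rpl39l (-5.61) were lower. In both lines 622 genes were higher and 712 lower by at least 2-fold, 12.8% of 10407, and limma called 0 (1212 at an unadjusted p under 0.05, smallest adjusted p = 0.151). Glycolysis and hypoxia genes were higher (median 0.43 over 26, 6 adjusted over the list alone), as was mesoderm (0.73 over 16). Lower lists were late germ cells (-0.92 over 23, 5 adjusted over the list alone), primitive endoderm (-1.56 over 7, 1 higher and 2 lower alone), ER and amino acid stress (-0.86 over 16, 4 lower and 1 higher alone), DNA methylation (-0.66 over 16, 0 alone), LIF and BMP signalling (-0.44 over 19, 0 alone) and p53 targets (-0.36 over 19, 1 alone). Naive and core pluripotency had 10 and 2 members past limma adjusted over the list alone. The p53 call was lost with no filter and with quantile normalization, and primitive endoderm with a stricter filter; 1 sphere array alone gave 2130 genes without line 21 and 2700 without line 42.

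Line 21 ES cells with and without 4OHT were compared for the effect of the active kinase in ES cell culture, with 1 array each and no replicate check. Genes of the amino acid and ER stress response were higher with 4OHT (median log2 1.11 over 16 members, 9 at least 2-fold higher). Ddit3, the stress transcription factor CHOP, read 297 without and 3073 with 4OHT (9.39-fold), Chac1, which degrades glutathione, 258 and 1660.4, and the regulators Atf3 and Atf5 were 5.72-fold and 6.11-fold higher. Nupr1, another stress-response gene, was 14.1-fold higher (93.8 and 1467), Stra8, a gene of meiotic entry, 9.86-fold (50.7 and 559.8) and Mthfd2, a mitochondrial folate enzyme, 6.88-fold. The naive pluripotency list had a median of 0.00 over 20 and the core list of -0.24 over 14. Nanog, Klf4 and Zfp42 read 3839, 1090.4 and 15996 with 4OHT against 5479.7, 1573 and 14177 without.

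Of 9852 genes, 251 were at least 2-fold higher and 236 lower with 4OHT (4.94%). The split was 347 to 173 under quantile normalization and 362 to 166 without centring, and the total was 751 with no filter and 313 with a stricter one. limma with the spread of the sphere lines called 0 (147 at an unadjusted p under 0.05 against 492.6 by chance). Other top genes were Grm3 (log2 3.22), Gpr135 (2.68) and Wdr20 (2.62, another probe 0.13) on the higher side. On the lower side were Ppig (-3.05), a prolyl isomerase, Kcnk1 (-2.81), Galnt12 (-2.63), Enpp2 (-2.56), Rsph3a (-2.56), the immunoproteasome subunit Psmb8 (-2.55), Kit (-2.49), Cd2 (-2.47), Slc27a2 (-2.42) and Fgf15 (-2.41).

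Further lists higher with 4OHT were p53 targets (0.33 over 19), in which Cdkn1a, a cell cycle inhibitor, read 199 and 692 and Mdm2 1201 and 2985, primitive endoderm (0.77 over 7), adipocyte genes (1.21 over 4), imprinted genes (0.21 over 17), late germ cells (0.21 over 24) and trophectoderm (0.34 over 9). Lower were early PGCs (-0.34 over 22), with Kit, Ifitm1 (-2.03) and Dppa3 (-1.47) at least 2-fold lower, and primed epiblast (-0.34 over 14), with Otx2 (-1.50), Lefty1 (-1.35) and Dnmt3b (-1.27). So were Myc targets (-0.36 over 19), with Mycn at 3684 and 806, glycolysis and hypoxia (-0.40 over 25), LIF and BMP signalling (-0.46 over 17), adhesion (-0.48 over 16), with the splicing regulator Esrp1 (-1.75), and OP9 stroma (-0.38 over 10). With no filter the calls of OP9 stroma, adipocyte and imprinted genes were lost and the trophectoderm median turned to -0.0076; trophectoderm was also lost under quantile normalization and the stricter filter, and primitive endoderm under the stricter filter.

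Reverted cells were compared with spheres to ask what changed on return to ES conditions. Zfp42 was 37.3-fold, Tbx3 33.5-fold and Klf4 11.4-fold higher in reverted cells, and the pluripotency lists lay above spheres (core 1.69 over 14, naive 1.70 over 21, with 7 and 12 members at least 2-fold higher against both lines). The genes highest in spheres were lower, among them Pygl (log2 -5.24), Fitm1 (-4.71), Fabp4 (-4.55), Xlr3b (-4.37), Mogat2 (-4.07) and Rab6b (-4.00). Ankrd37 (-3.35) and Egln3 (-3.19) led a glycolysis and hypoxia list with a median of -0.35 over 25 (6 lower against both lines, 4 adjusted over the list alone). Trh, a hypothalamic hormone gene, was 106.1-fold higher, with 23511 in reverted cells and 862 and 54.0 in spheres, followed by the neurofilament gene Nefl (81.5-fold), Tgm1 (5.51), Ooep (5.31), the interferon-induced chemokine Cxcl10 (5.01) and Acsbg3 (4.91). Pla1a (-4.50), the replication origin gene Orc6 (-4.27), Prap1 (-4.00) and Rflna (-3.83) were also lower.

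Against both sphere lines 600 genes were at least 2-fold higher and 435 lower in reverted cells, of 10328. limma called 0 (920 at an unadjusted p under 0.05, 516.4 by chance, smallest adjusted p = 0.219), and 1 sphere array alone gave 2283 genes without line 21 and 1704 without line 42. Interferon response genes were higher (1.24 over 13, 1 adjusted over the list alone), with Psmb8 (4.68) and Oas1a (4.25), as were adhesion genes (0.97 over 17), with the epithelial cadherin Cdh1 at 2.12 and Zeb1, a repressor of epithelial genes, at -2.72 (3 higher and 1 lower adjusted over the list alone). OP9 stroma genes (0.81 over 18, 4 adjusted over the list alone) were led by the smooth muscle genes Tagln (4.71) and Acta2 (3.05), and embryonic fibroblast genes had a median of 0.66 over 10. The other higher lists were primitive endoderm (1.12 over 8, 1 higher and 1 lower adjusted over the list alone) and, each with 0 adjusted over the list alone, primed epiblast (1.13 over 15), DNA methylation (0.50 over 17), LIF and BMP signalling (0.63 over 18), early PGCs (0.34 over 21) and late germ cells (0.28 over 21); adipocyte genes were lower (-1.24 over 5, 2 adjusted over the list alone). Core and naive pluripotency had 3 and 7 members past limma adjusted over the list alone. The fibroblast call was lost with a stricter filter, and that of late germ cells with either filter or the other pseudocount.

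Reverted cells were also set against ES cells without 4OHT, 1 array each with no replicate check, to see what still differed. Klf4, Zfp42 and Nanog were within 2-fold (1336, 11370.2 and 4538 against 1573, 14177 and 5479.7). The mesoderm factor T was 12.1-fold higher (22.6 and 305), Fgf5 4.50-fold and Cxcl10 32.6-fold. Among imprinted genes, the maternally expressed cell cycle inhibitor Cdkn1c was 69.8-fold lower (1367 and 20.0) and Phlda2 was lower by -2.80, while H19, also maternally expressed, was higher by 2.83. The paternally expressed Plagl1 (3.56), Peg3 (2.53) and Mest (2.05) were higher, and the list had a median of 0.35 over 17 with 6 higher and 4 lower. Stra8 (-3.74) and Sohlh2 (-3.18), both of gonadal germ cells, led a late germ cell list with a median of -0.49 over 23.

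**Figure D3:**
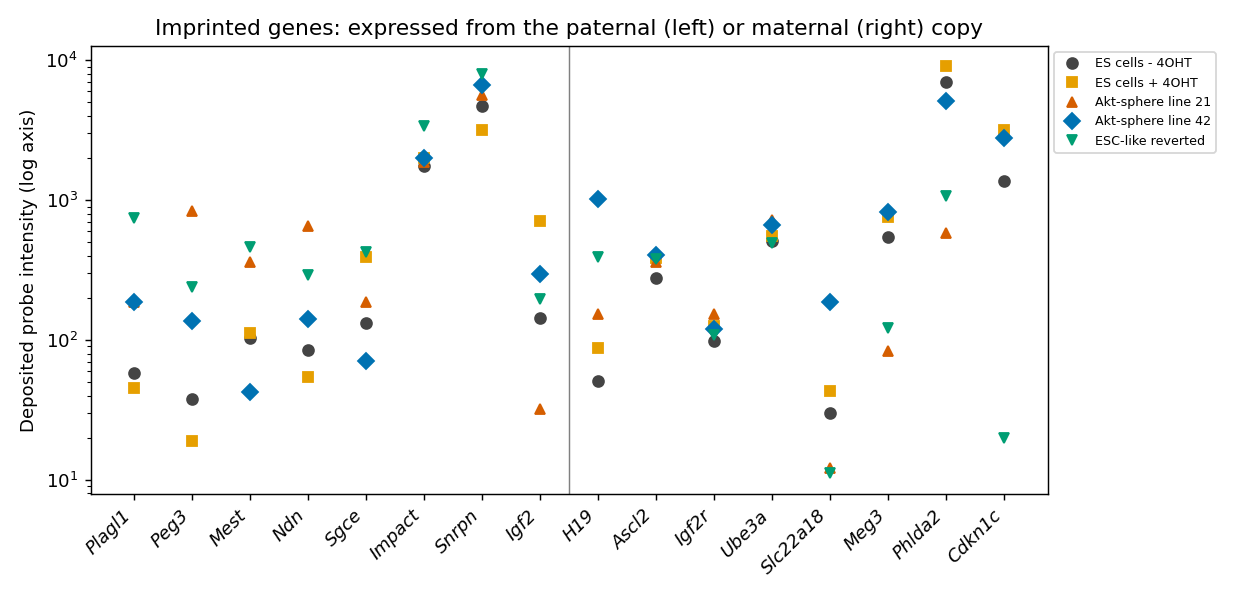
Deposited probe intensity (log axis) of 16 imprinted genes on each of the 5 arrays, 1 symbol per array, with genes expressed from the paternal copy on the left and from the maternal copy on the right of the grey line. In reverted cells Cdkn1c reads 20.0 against 1367 in ES cells without 4OHT, and Plagl1 740.4 against 57.7; line 21 spheres have no value for Cdkn1c.

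Of 9939 genes, 515 were at least 2-fold higher and 629 lower in reverted cells (11.5%); the majority turned to 634 higher and 519 lower under quantile normalization and to 633 and 529 without centring. limma with the spread of the sphere lines called 0 (329 at an unadjusted p under 0.05 against 496.95 by chance). Other top genes were Nefl (log2 4.22), the fibroblast-associated S100a4 (4.03), Tm4sf1 (3.79), the matrix genes Efemp1 (3.69) and Bgn (3.54), Gbp2 (3.51) and Krt28 (3.46, another probe -1.04). Lower were Pla1a (-5.49), Rpl39l (-5.24), the polarity gene Llgl2 (-5.03), Khdc3 (-4.80), Orc6 (-4.65), the nuclear pore gene Nup107 (-4.44), Defcr3 (-4.38) and Ak7 (-4.37). Zscan4c, a gene of the 2-cell-like state, read 1058 in ES cells without 4OHT and had no value in reverted cells. Further higher lists were mesoderm (0.49 over 14), with Msx1 (2.51), OP9 stroma (0.87 over 16), embryonic fibroblasts (0.62 over 10), adhesion (0.53 over 17), with the desmosomal Dsp (2.50), primed epiblast (0.31 over 15) and ER and amino acid stress (0.29 over 16). Lower were core (-0.45 over 14) and naive pluripotency (-0.33 over 22), glycolysis and hypoxia (-0.32 over 24) and histone modifiers (-0.37 over 22). The stricter filter ended the calls of ER stress, fibroblasts and late germ cells, no filter those of ER stress, primed epiblast and glycolysis, and quantile normalization those of glycolysis and naive pluripotency (-0.14).

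The sphere lines differed from each other, with 1 array per line and no replicate check. In line 42 spheres Zscan4c read 12913 against 3.59 in line 21 spheres, Dppa3, a gene of PGCs and naive cells, was 39.6-fold higher and Dppa4 55.8-fold higher. Line 21 spheres had more of the mesoderm genes T (193 and 19.9) and Msx1 (337 and 30.9) and of the matrix genes Mgp (328 and 10.1) and Fn1 (1386 and 168). At least 2-fold apart were 782 genes higher and 777 lower in line 42, 15.7% of 9954. Hesx1 (log2 5.07), Mep1b (5.46), Rpl39l (5.41), Fthl17e (5.29), the oocyte homeobox gene Obox1 (4.85), Olfr106-ps (4.68) and Fmr1nb (4.68) were also higher in line 42. Lower there were Erbin (-5.76), the transcription factor Bcl11a (-5.57), Nefl (-5.39), the RNA-binding Igf2bp3 (-5.02), S100a4 (-4.91), the neural factor Olig3 (-4.74), the Y-linked Zfy1 (-4.72), Hs6st2 (-4.54) and Fgf15 (-4.37). Core pluripotency (1.35 over 13), late germ cells (0.87 over 19), p53 targets (0.59 over 18), FoxO targets (0.40 over 17) and the 2-cell-like list (1.65 over 3) were higher in line 42. Primed epiblast (-0.90 over 14), OP9 stroma (-0.91 over 15), adhesion (-0.63 over 14), neuroectoderm (-0.58 over 10), mesoderm (-0.44 over 15), histone modifiers (-0.36), LIF and BMP signalling (-0.32) and the cell cycle (-0.17) were lower. A stricter filter ended the calls of late germ cells, FoxO targets, neuroectoderm, mesoderm, LIF and BMP signalling and the cell cycle, and left the 2-cell-like list with under 3 members, so 7 lists were called against 13, of which 6 were shared. No filter ended that of neuroectoderm and FoxO targets and took the 2-cell-like median to 0.89, and quantile normalization ended those of FoxO targets and LIF and BMP signalling.

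To place reverted cells between ES cells and spheres, 976 genes at least 2-fold higher and 1106 at least 2-fold lower in line 42 spheres than in ES cells with 4OHT were measured on the remaining arrays. The higher genes had a median log2 difference from ES cells without 4OHT of 0.90 in line 21 spheres and 0.18 in reverted cells, so 20.1% remained. The lower genes had -1.05 and -0.20, so 19.2% remained. Of the 2 sets, 81.1% and 77.6% lay within 2-fold of ES cells without 4OHT in reverted cells. These shares alone do not measure a return. Of all 9939 genes compared between those arrays, 11.5% were at least 2-fold apart. In line 21 spheres the median of the higher genes, 0.90, was itself under 2-fold. Under quantile normalization 30.4% of the higher and 9.71% of the lower difference remained. With genes chosen on line 21 spheres and measured against those of line 42, the same ratio was 60.5% for the higher and 70.4% for the lower genes. Reverted cells did not come from line 42, so there it is not a share that remained.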

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

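All tests weighed here were chosen after the results they bear on were seen. Of 97 named genes, 9 lay at least 2-fold from ES cells without 4OHT in opposite directions in the 2 sphere lines, with 1 array per line, and these differences were not tested. As log2 differences of line 42 minus line 21 spheres, they were 5.31 for Dppa3, 4.85 for Obox1, 4.68 for Olfr106-ps and 3.59 for Krt28. They were -5.76 for Erbin, -5.57 for Bcl11a, -4.91 for S100a4, -4.72 for Zfy1 and -4.37 for Fgf15. All of these genes but Krt28 ranked among the named genes with the largest differences between the lines. Their number therefore follows largely from that choice and gives no rate over all genes. Another probe of Krt28 read -1.04 where this one read 3.46, in reverted cells against ES cells without 4OHT. Its difference between the sphere lines is not reported here. Outside the named genes, 322 of 3428 probes without a gene name (9.39%) were at least 2-fold apart from ES cells without 4OHT the same way in both sphere lines, 143 higher and 179 lower. Which transcripts these probes measure was not examined.

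Genes apart between the sphere lines kept the line 21 direction in reverted cells, which came from line 21 spheres: the 799 genes at least 2-fold lower in line 21 than in line 42 spheres had a median log2 difference of -0.60 from ES cells without 4OHT, under all random lists, and the 810 higher genes of 0.27, above all of them. A difference of line 42 or its array alone predicts no such shift on another array. Sphere cells left among reverted cells would carry every loss over alike. For genes lower in line 21 spheres alone, the median share of the loss still present was 68.1% (95% bootstrap interval 58.3% to 75.4%, 356 genes). For genes lower in both lines it was 37.9% (31.3% to 42.2%, 702 genes). The genes were chosen against ES cells with 4OHT, but the share was taken against those without. Small losses there give unsteady shares, so these medians cannot decide. Unchanged sphere cells would also carry over the largest rises in spheres. For ES cells without 4OHT, line 21 spheres and reverted cells, Mogat2 read 78.0, 2967 and 194, and Pygl 9.41, 334 and 8.42. Xlr3b read 363, 12143 and 553, while others, such as Cd59a (116, 2813 and 1000) and Chst1 (17.0, 414 and 211), stayed higher. Mogat2, Pygl and Xlr3b argue against unchanged sphere cells as the source of shares this large. Leftover sphere cells that had lost these transcripts stay open. Of the 799 lower genes, 28.7% were at least 2-fold lower in reverted cells, against 6.07% of all genes. Of the 810 higher genes, 17.3% were 2-fold higher, against 4.94% of all. RNA of feeder cells would raise their own transcripts and, on arrays scaled to a common median, dilute those that feeders lack. These shares therefore cannot exclude it. The OP9 stroma and fibroblast lists had medians of 0.87 and 0.62 on the reverted array. Of the first, 6 members were at least 2-fold higher and 1 lower, Thy1 (464 in ES cells without 4OHT, 230 in reverted cells). Of the second, 1 was higher, S100a4, and 1 lower, Vim (1870 and 567). Dilution would lower transcripts that feeders lack alike, but the core pluripotency genes Dppa5a and Dppa4 read 58362 and 49687, and 4619 and 1733. Dilution alone does not account for losses so uneven, but some feeder RNA stays open for both sets. For the lower genes a stable change in the line 21 sphere culture that reverted cells inherited may be behind the pattern, as a hypothesis, while a hybridisation batch shared by both arrays, which the labels do not give, stays open.

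Amino acid and ER stress genes were higher in ES cells with 4OHT (median log2 1.11 over 16 members). If 4OHT or the active kinase raised them in every culture, spheres kept in 4OHT would have them high too, but the medians against ES cells without 4OHT were -0.0646 in line 21 and -0.15 in line 42 spheres. Scaling of the arrays is also argued against, since the median was 1.18 under quantile normalization and 1.25 without centring. The state of a single dish, such as its density or the age of its medium, was not tested and stays open, as does a response to the kinase confined to ES cell culture. With 1 array on each side, a candidate explanation can be named but not chosen.

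Egln1, Egln3, Ankrd37, Adm, Ero1a and Fabp4 were higher in both sphere lines than in ES cells without 4OHT. The glycolysis and hypoxia list as a whole had a median of 0.15 there, within the central range of random lists. In both lines 8 of its members were at least 2-fold higher and 1 lower. The list was called higher against ES cells with 4OHT (0.43) and against all ES-type arrays together (0.32). OP9 stromal cells, which can form adipocytes, were removed only by plating for 30 min. Over Col1a1, Col1a2 and Col3a1, abundant in stromal cells, the median against ES cells without 4OHT was -0.14 in line 21 and -0.35 in line 42 spheres, but Col1a1 and Col3a1 (18.6 and 25.9 in ES cells, 17.5 and 19.8 in line 21, 17.0 and 10.0 in line 42 spheres) lay under the filter on dim probes. Col1a2 read 50.0 in ES cells, 101 in line 21 and 42.0 in line 42 spheres, Col5a1 86.7, 310.3 and 171, and Adipoq 6.73, 12.2 and 12.0. Against ES cells without 4OHT, the adipocyte list had a median of 1.36 in spheres, but also of 1.21 in ES cells with 4OHT. For spheres against ES cells with 4OHT its median was 0.25, within the central range of random lists. Mgp, Bgn and S100a4 reached 328, 143 and 279.6 in line 21 but 10.1, 10.6 and 8.69 in line 42 spheres. Stromal RNA and expression by the sphere cells therefore cannot be told apart here, because dim collagen probes decide nothing, while Fn1 (1904 in ES cells, 1386 and 168 in spheres), Acta2 (476, 80.7 and 62.4), Tagln (148, 16.0 and 36.0) and Thy1 (464, 24.8 and 16.1) were lower in both lines from levels that would hide a small share, and Plin1 read 25.2, 25.2 and 32.4. Low oxygen inside the floating colonies may raise the members of the glycolysis and hypoxia list that rose, a hypothesis that no measurement here tests. Others of that list did not rise. Slc2a1 read 3186 in ES cells without 4OHT and 1241 and 2249 in spheres of lines 21 and 42, and Pdk1 1254, 866 and 973.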

How the results depend on the processing

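The setting that replaces empty cells with the lowest listed value of the array was chosen after seeing the data; the other settings were planned. Among named genes at least 2-fold apart in the main setting, 11 alternative values fell under 2-fold and 0 changed sign. The other 1748 values were counted as unchanged. They include genes under 2-fold in the main setting, whose sign was not checked. Of the alternative values of lists outside the central 95%, 392 kept their call, 36 lost it and 1 changed sign, trophectoderm with 4OHT, with -0.0076 without a filter. For spheres against the 3 ES-type arrays, limma called 239 to 280 genes under other scalings, filters, pseudocounts, probe rules, an intensity trend and replaced empty cells, and 281 without reverted cells. It called 93 to 148 without 1 of the sphere arrays, 32 without ES cells with 4OHT and 0 without ES cells without 4OHT; fewer arrays leave fewer degrees of freedom, and why the ES arrays weigh unequally was not tested. For spheres against ES cells without 4OHT, ES cells with 4OHT and reverted cells, limma called 0 under each alternative (964, 1212 and 920 genes at an unadjusted p under 0.05 as reported), where 2-fold in both lines gave 1082, 1334 and 1035 genes, and 958 against the 3 ES-type arrays. With 1 sphere array that rule gave 1890 to 2264, 2130 to 2700 and 1704 to 2283 genes, since fewer arrays have to pass. In simulated data with both lines, it called 563 unchanged genes against ES cells without 4OHT and 168 against the 3 ES-type arrays.

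Between single arrays, a 3-fold threshold gave 129 genes for 4OHT, 366 for reverted cells against ES cells without 4OHT and 572 between sphere lines, fewer by construction. limma with the spread of the sphere arrays called 0 genes for 4OHT and 0 for reverted cells (147 and 329 at an unadjusted p under 0.05). For 4OHT, 313 genes were left by a stricter filter and 751 with none, since dim probes then count. Between sphere lines, a stricter filter gave 7 shifted lists against 13; the cause was not tested. With genes chosen on line 21 spheres, the median in reverted cells was 60.5% of that in line 42 spheres for higher genes (0.37 against 0.61). For lower genes it was 70.4% (-0.50 against -0.71). Reverted cells did not come from line 42, so these ratios are not shares kept, and their cause was not tested. Probes near the floor of about 3 limit what fold can be seen. No paired analysis was possible because no 2 groups have repeated samples that share a line or culture.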

Other observations

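The tests of imprinted genes, and the genes described here, were chosen after their values were seen. The signalling inhibitor gene Spry2 read 154 in ES cells without 4OHT, 138 and 38.6 in spheres of lines 21 and 42 and 499 in reverted cells, and the FGF target Dusp6 758, 517, 268 and 833. Among cell cycle genes, Pcna, a replication clamp, ranged from 15071 to 20909 over the 5 arrays and Cdk1 from 4449 to 5931, while Cdc20 ranged from 1678 to 7607 and Mcm7 from 2323 to 7211. The G1 cyclin Ccne1 read 650.4 and 1865 in spheres against 2514 to 3728 on the other arrays.

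Among lipid genes, the desaturase Scd2 read 3528 and 3146 in spheres and 872 to 1515 on the other arrays, and the sterol and lipid regulator Srebf1 211 and 235 against 67.8 to 113. Among germ cell genes, Dnd1, which protects germ cell transcripts, read 2142 and 393 in spheres of lines 21 and 42 against 172 to 223, Tdrd12 of the transposon defence 68.1 and 446 against 651 to 737, and Gtsf1 12.9 and 25.6 against 33.5 to 197. The demethylase Tet1 read 384 and 198 in spheres and 628 to 765 elsewhere, and Uhrf1, which guides maintenance methylation, 1334 and 1398 against 1785 to 2667.

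A hypothesis is that imprints changed in line 21 cells during or after sphere culture, so that genes expressed from the paternal copy gained and those from the maternal copy lost expression. In reverted cells against ES cells without 4OHT, 8 paternally expressed genes had a mean log2 difference of 1.65, higher in 8 of 8, and 8 maternally expressed genes of -1.19, lower in 5 of 8 (exact two-sided permutation p = 0.00932 over 12870 splits, 0.0373 adjusted over 4 arrays). The difference between the classes was 1.82 in line 21 spheres (exact two-sided permutation p = 0.0960, adjusted 0.192), -0.68 in line 42 spheres (p = 0.340, adjusted 0.452) and -0.33 in ES cells with 4OHT (p = 0.452, adjusted 0.452). The test in line 21 spheres had 8 paternally and 7 maternally expressed genes, because Cdkn1c had no value there. At the lowest listed value of that array, Cdkn1c would lie 402-fold below ES cells without 4OHT. The values of Cdkn1c, Phlda2, Plagl1, Peg3 and Mest in reverted cells gave rise to the idea, and without these 5 the difference was 1.12 (exact two-sided permutation p = 0.210 over 462 splits, 5 of 5 paternally expressed genes higher and 3 of 6 maternally expressed genes lower). The hypothesis thus stays open: imprinted genes lie in clusters and are not independent, the comparisons share the array of ES cells without 4OHT, and no allele or methylation was measured here. On the reverted array the OP9 stroma and embryonic fibroblast lists had medians of 0.87 and 0.62, though 1 member of each, Thy1 and Vim, was at least 2-fold lower. Feeder RNA therefore also stays open for the imprinted genes that were higher there. Snrpn, also paternally expressed, read 4672 in ES cells without 4OHT and 7914 in reverted cells, and Meg3, maternally expressed, 545 and 122, while the maternally expressed H19 went the other way, with 50.6 and 393. Zfp57, which protects imprints, had no value in spheres and read 50.5 and 42.0 in ES cells without 4OHT and reverted cells, and its partner Trim28 read 948 and 932 in spheres against 1786 to 2204 elsewhere.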
